A study of Mus musculus with 20 samples.

How the data were processed

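Hearts of mice with the MuRF1 gene (MuRF1 +/+) and of MuRF1 knockout mice (MuRF1 -/-) were profiled on 20 Agilent whole-genome mouse arrays with 2 colours. Per the labels, heart RNA was extracted with a Qiagen AllPrep kit, 50 ng were amplified with Agilent's low-input kit, and heart RNA carried Cy5 while a pool of whole C57BL/6 pups of postnatal day 1 carried Cy3 on every array. No dye swap is labelled, so a dye effect of a gene is part of its level but not of a difference between groups. The protocol text of the labels names Cy3 for the labelling of heart RNA, while the channel labels name Cy5. The channel labels set the direction used here, and all arrays ran the same way, with correlations of log2 ratios between any 2 arrays from 0.746 to 0.983.

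The deposited scanner files hold spot intensity, written by Agilent Feature Extraction 9.5.3.1 for array design 014868 per the file headers. The mean intensity and the median local background of each spot and channel were deposited without normalization. The other columns used from the deposited files were flags of 0 or 1 per spot, for being well above background, saturated or an outlier. Agilent's log10 ratio of Cy5 over Cy3 was deposited too, after background subtraction, detrending and dye normalization per the file headers. The deposited series matrix holds the authors' log2 values of the same arrays, whose processing is not given in the sources used here. Set against Agilent's ratio on bright probes, its columns had slopes of 0.989 to 1.01 on the log2 Cy5/Cy3 scale, so scale and direction were settled, and column medians ran from -0.0060 to 0.0093.

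Spot intensities were background-corrected with normexp (offset 50), and log2 ratios of heart over reference were normalized within each array by loess in limma 3.58.1 under R 4.3.3, with version 1.17.8 of data.table. Control spots had weight 0 in loess and were then left out, and spots marked as outliers (105 to 423 per array) were treated as missing. The background fit departs from the plan, which would have fitted normexp on all spots. Spots whose local background exceeded their own signal by more than 50 were left out of it and treated as missing, which was the case for 7 spots, all on replicate 2 of the MuRF1 -/- chow group. With all spots in the fit, the SD of that array's log ratios was 0.400 in place of 0.597. This choice was made after seeing the arrays' spread and before any comparison. The planned fit with all spots is an alternative here. It lowers the count of every comparison except the differences of the responses. Comparisons without the MuRF1 -/- chow group fall too, as 8 weeks in MuRF1 +/+ (2036 to 1205) and genotype at 3 weeks (58 to 21). It raises the 8-week difference from 1 to 6 and turns the 8-week correlation between genotypes negative. In the series matrix that array had an SD of 0.419 and correlated at 0.999 with the planned fit (0.887 with the main one). The matrix and the planned fit are thus not independent.

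Spots of a probe were averaged, leaving 41174 probes from 43379 spots. Names came from the accessions in the files through a RefSeq table of assembly GRCm38.p6, which was used for names and for gene neighbours only. Of the probes, 22951 were named by accession, 6659 carried a current symbol, 3109 were updated through a synonym and 8455 kept the name in the files, giving 27670 names. Each gene was represented by its probe with the brightest mean heart signal, and was tested if that probe was well above background in the heart channel on at least 3 arrays, which left 14567 genes. Of 431 pairs of a named gene and a comparison past the threshold, 181 had another measured probe, and in 31 of these another probe had the opposite sign. Genes with near-identical copies, such as Acot1 and Acot2 or Mt1 and Mt2, are uncertain, since a probe can bind both transcripts.

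Heart probes well above background made up 34.0% to 51.9% of each array and reference probes 56.8% to 64.7%, and 0 heart spots were saturated on any array. The number of arrays, 3 or 4 per group, limits the precision. The labels call the hearts biological replicates and give no sex, litter or date. The series text speaks of 2 to 3 replicates and gives 3 to 8 weeks as an age, whereas the samples number up to 4 per group and their labels give the weeks as time on the diet, which was followed here. The arrays came from 5 slides of 4 arrays, each slide scanned as a unit, and every group was spread over at least 3 slides. Slides were told apart by their scan. For 4 arrays the header names another slide, so every value with slide as a block or within slides rests on the scan.

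The groups, the 12 comparisons, the tests, the gene lists and the first set of alternatives were chosen before the data were examined. One limma model with the 6 group means was fitted to all 20 arrays, with a trended prior variance and Benjamini-Hochberg adjustment of each comparison over all tested genes at 0.05. Changes are given as log2 differences ± SE from this model. In the comparisons, "averaged" means the mean over both genotypes (and, against chow, over 3 and 8 weeks) or, for genotype, over the 3 diet groups. Where a transcript was not well above background on any array of a group, its fold is a lower bound, "at least" N-fold. The bound sets the measured group's mean against, per array, the higher of the probe's own signal and the lowest signal well above background, and it is open to dye bias. It is computed on the heart channel after loess and Aquantile normalization, so it can lie above the fold of the ratios to the reference, which are normalized otherwise.

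In all, 24 lists of genes for pathways and cell types were written down, of which 23 had the 5 or more measured members needed and were tested with limma's camera at a preset correlation of 0.01. That made 276 tests adjusted together, of which 49 passed. With a correlation estimated for each list, 0 passed in limma's camera, so each list call is given with its adjusted p under both. Within-slide list values are differences of the lists' mean log2 ratios between arrays of one slide.

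The genes named are Trim63, the 12 largest rises and falls of each averaged fenofibrate or genotype comparison, and the 3 largest rises and falls of the other comparisons. Where 5 or fewer genes passed, all were eligible. For each list, up to 4 members past the threshold with the smallest p, or the 2 brightest members where none passed, were added. Where no gene passed, the 3 with the smallest p are given. Clone names, predicted genes and bare accessions count in totals only, and a few genes that the rule names are not reported here.

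The alternatives of that first set were slide as a fixed or a random block, the replicate number as a block, no background subtraction, Aquantile normalization between arrays, Agilent's own log ratio, the heart channel alone with quantile normalization, and the submitters' series matrix. Others were no filter on dim probes, a strict filter (well above background in both channels on all 20 arrays), the mean of all probes of a gene, only the groups of a comparison in the fit, array weights, and leaving out each array in turn. The added alternatives, chosen after seeing the data, were the normexp fit with all spots, the level of Y-linked transcripts as a covariate, leaving out 2 arrays that stood apart (MuRF1 +/+ 8 weeks replicate 2 and MuRF1 -/- 3 weeks replicate 4), and leaving out the 3-week arrays.

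The model was tested on simulated data with 100 of 14319 genes changed by each size. For a log2 change of 0.5 it recovered 49% in the 8-week comparison of MuRF1 +/+, 62% in that of MuRF1 -/-, 52% for genotype on chow, 93% for genotype averaged and 26% for the difference of the 8-week responses. For a change of 1 it recovered 92%, 95%, 90%, 99% and 76% in the same order, with 2, 7, 8, 11 and 3 false calls. A list shifted by 0.5 had an adjusted p of 1.83e-28 in limma's camera, and 0 other lists were called. The simulation does not show which correlation, preset or estimated, holds in the real data.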

Results

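Heart RNA was measured on 20 arrays, each holding 1 heart against a common reference of whole newborn mice. The animals either carried MuRF1 (MuRF1 +/+), the muscle ubiquitin ligase encoded by Trim63, or lacked it (MuRF1 -/-). They ate chow or chow with 0.05% (w/w) fenofibrate, a drug that activates the nuclear receptor PPAR alpha. In each genotype there were 3 hearts on chow, 4 after 3 weeks of fenofibrate and 3 after 8 weeks. The series addresses the part MuRF1 plays in the heart growth seen with fenofibrate. The chow hearts belong to 8 weeks, so the 3-week hearts have no control of matched duration, and in each genotype the 3-week and 8-week responses share the same chow hearts. The number of arrays limits the precision. The share of probes well above background in the heart channel was 38.8% to 44.2% on chow arrays and 34.0% to 43.0% on 8-week arrays. On the 3-week arrays it was 40.8% to 51.9%, except for 34.3% on MuRF1 -/- replicate 4.

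Sex-linked transcripts differed with diet. Ddx3y and Eif2s3y, which are encoded on the Y chromosome, were both well above background in 3 of 3 chow hearts of each genotype, in 0 of 4 MuRF1 +/+ hearts at 3 weeks and in 0 of 3 at 8 weeks. In MuRF1 -/- both were above background in 0 of 4 hearts at 3 weeks and in 2 of 3 at 8 weeks. Xist, the RNA of the inactive X chromosome, was low on chow and high at 3 weeks. In MuRF1 +/+ its log2 ratio to the reference was -4.06 ± 0.19 (SD, n = 3) on chow, -0.30 ± 0.22 (n = 4) at 3 weeks and -1.88 ± 0.91 (n = 3) at 8 weeks. In MuRF1 -/- it was -3.85 ± 0.33 (n = 3), 0.0076 ± 0.17 (n = 4) and -3.43 ± 0.67 (n = 3). At 8 weeks Y-linked and Xist levels did not mirror each other in every heart, since MuRF1 +/+ replicate 1 and MuRF1 -/- replicate 2 had low Y-linked means (-0.92 and -0.81) together with Xist at -2.70 and -2.72. The labels give no sex. The chow comparisons of MuRF1 +/+ and of 3-week MuRF1 -/- hearts thus set hearts with both Y-linked transcripts above background against hearts without both. There a Y-linked covariate cannot part sex from diet. In the genotype comparison at 8 weeks, 2 of 3 MuRF1 -/- hearts had both and 0 of 3 MuRF1 +/+ hearts did. Replicate 2 of the 8-week MuRF1 +/+ group and replicate 4 of the 3-week MuRF1 -/- group stood apart from the other arrays on the first 2 principal components, which held 43.9% and 22.1% of the variance.

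**Figure D1:**
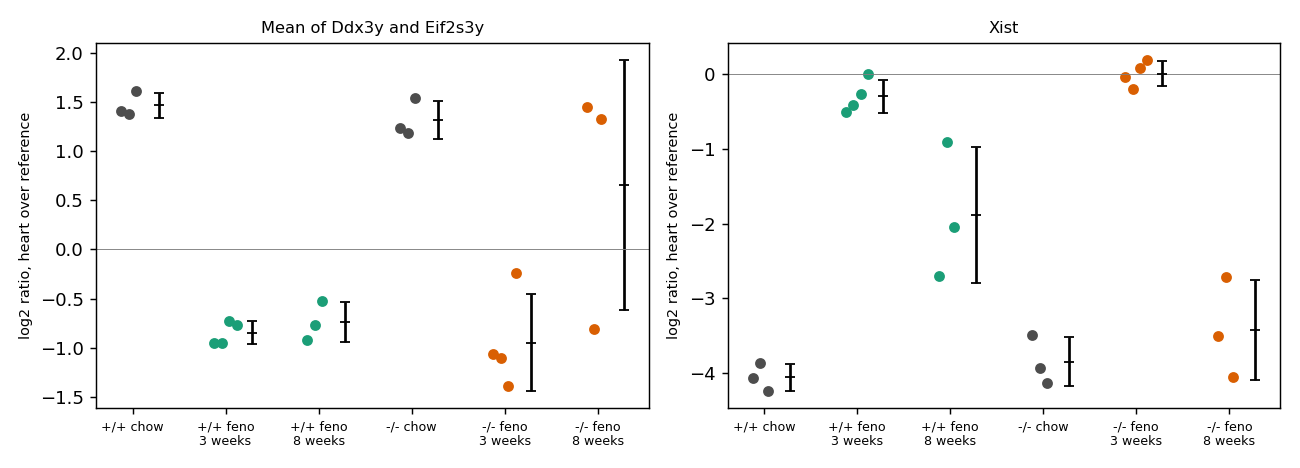
Log2 ratio of heart to reference for the mean of Ddx3y and Eif2s3y (left) and for Xist (right) in the 6 groups; points are arrays and bars are group means ± SD. Chow hearts of both genotypes have the high Y-linked and low Xist levels, and the 3-week hearts the reverse.

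Trim63 was lower in every MuRF1 -/- heart than in any MuRF1 +/+ heart. At the tested probe the 10 MuRF1 -/- arrays lay between -1.19 and -0.49 and the 10 MuRF1 +/+ arrays between 0.79 and 2.85 on the log2 scale. Averaged over diets, Trim63 was 10.1-fold lower in MuRF1 -/- (log2 -3.34 ± 0.18, limma adjusted p = 4.43e-09), and it was 11.3-fold lower on chow, 11.4-fold lower at 3 weeks and 7.97-fold lower at 8 weeks. In MuRF1 +/+ the level was 2.49 ± 0.10 (SD, n = 3) on chow, 2.56 ± 0.30 (n = 4) at 3 weeks and 2.02 ± 1.08 (n = 3) at 8 weeks, and no diet effect passed at this probe. A dimmer Trim63 probe was not well above background on any MuRF1 -/- array. It was higher after 3 weeks in MuRF1 +/+ (log2 1.00 ± 0.078, adjusted p = 4.83e-07 in a fit of all probes), while the tested probe differed by 0.076 ± 0.30 there. Where the probes lie relative to the deleted part is not given in the sources used here. Within single slides, genotype differences at the tested probe were -3.61 and -3.56 on chow, -4.00 to -3.08 at 3 weeks and -3.80 to -3.42 at 8 weeks. The 8-week call was lost when only its 2 groups entered the fit.

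**Figure D2:**
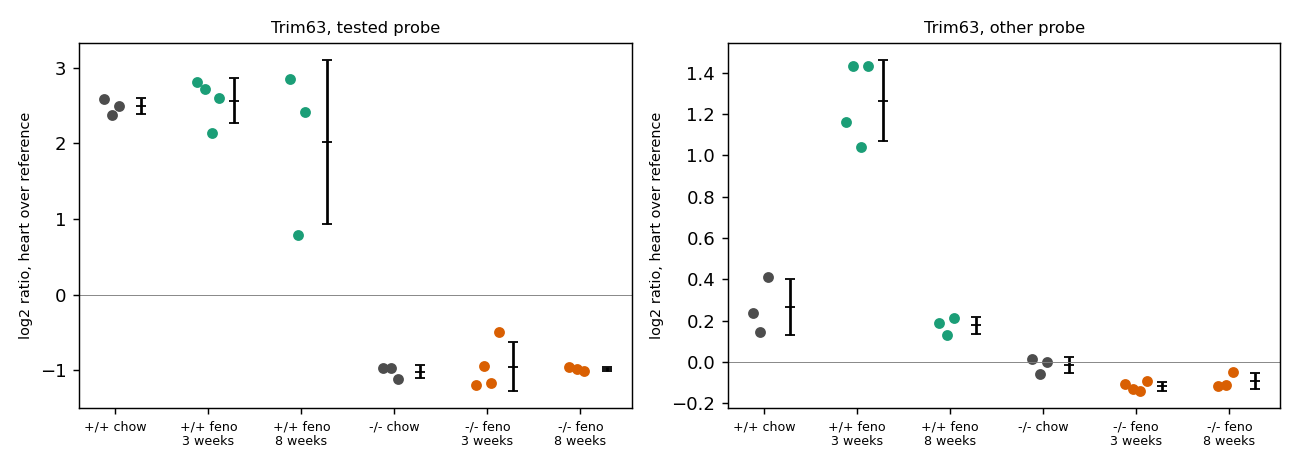
Log2 ratio of heart to reference for Trim63 at the tested probe (left) and at a dimmer probe (right) in the 6 groups; points are arrays and bars are group means ± SD. At the tested probe all 10 MuRF1 -/- arrays lie at -0.49 or below and all 10 MuRF1 +/+ arrays at 0.79 or above.

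After 8 weeks of fenofibrate, MuRF1 +/+ hearts had 7.06-fold more Pdk4, the kinase that inhibits pyruvate dehydrogenase (log2 2.82 ± 0.36, n = 3 against 3, adjusted p = 0.000105). Acot1, a cytosolic acyl-CoA thioesterase, rose 6.11-fold (2.61 ± 0.39), Mt2, a metallothionein, rose 8.68-fold (3.12 ± 0.45), and Angptl4, an inhibitor of lipoprotein lipase, rose 3.11-fold (1.64 ± 0.36). Nmrk2, the nicotinamide riboside kinase of striated muscle, fell 6.00-fold (log2 -2.58 ± 0.35) and Cyp1a1, a target of the aryl hydrocarbon receptor, fell 4.34-fold (-2.12 ± 0.25). Of PPAR alpha target genes, 7 of 28 measured rose, 1 fell and 20 did not pass, or 8 and 2 adjusted over the list alone, and the list as a whole did not pass (median 0.20, adjusted p = 0.0718). Cpt1a, the liver-type carnitine palmitoyltransferase, was among those that rose (0.38 ± 0.086). The Y-linked Eif2s3y (log2 ratio -2.32 ± 0.42) and Ddx3y (-2.08 ± 0.37) fell below background, which on the heart channel scale is at least 5.12-fold and 4.17-fold lower.

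Muscle genes of MuRF1 +/+ hearts moved in both directions at 8 weeks. Actc1, the cardiac actin, fell 3.13-fold (log2 -1.65 ± 0.21), while Myom2, an M-band protein, rose 2.34-fold (1.23 ± 0.16), and Ttn (1.30 ± 0.32) and Myh7, the slow myosin heavy chain (1.68 ± 0.44), rose as well. Of 22 sarcomere genes, 3 rose and 2 fell, and the list did not pass (adjusted p = 0.705), its median of 0.15 opposing the sign of the test. Of 22 hypertrophy and fetal genes, 2 rose and 3 fell (median 0.10 against a negative test, adjusted p = 0.943), with Ccn2 up (2.09 ± 0.46) and Xirp2 down (-0.76 ± 0.16). Calcium handling and conduction genes fell as a list (6 of 18 fell, 9 adjusted over the list alone, median -0.53, adjusted p = 0.00156, and adjusted p = 0.816 with an estimated correlation). Among them were Casq2, the calcium buffer calsequestrin (-1.24 ± 0.22), and the potassium channel gene Kcnq1 (-1.02 ± 0.21). Of ubiquitin ligase and proteasome genes, 6 rose and 2 fell of 27, without a list call (adjusted p = 0.352). Fbxo32, the muscle ubiquitin ligase atrogin-1, rose 2.23-fold (1.16 ± 0.22) and the F-box gene Fbxo31 rose 1.60-fold (0.67 ± 0.14).

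Glucose uptake and glycolysis genes fell as a list in the same hearts (1 rose and 9 fell of 24, 1 and 12 adjusted over the list alone, median -0.37, adjusted p = 0.00149, and adjusted p = 0.323 with an estimated correlation). Pdhb, a pyruvate dehydrogenase subunit (log2 -1.13 ± 0.29), and Pkm, pyruvate kinase (-0.60 ± 0.16), were among those that fell. Endothelial genes rose (8 of 20, 10 adjusted over the list alone, median 0.62, adjusted p = 0.000169, and adjusted p = 0.89 with an estimated correlation), with the water channel gene Aqp1 (1.5 ± 0.37), von Willebrand factor Vwf (1.01 ± 0.24) and the tight junction gene Cldn5 (0.83 ± 0.20). Extracellular matrix and fibroblast genes rose (5 of 26, 7 adjusted over the list alone, median 0.35, adjusted p = 0.00537, and adjusted p = 0.892 with an estimated correlation), with the collagen gene Col4a1 (0.99 ± 0.21). Immediate early and heat shock genes rose (4 rose and 1 fell of 18, 8 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.0129, and adjusted p = 0.889 with an estimated correlation), with Nr4a1 up (1.45 ± 0.36) and Ier3 down (-0.87 ± 0.15). Adipocyte genes rose (3 of 15, median 0.33, adjusted p = 0.0212, and adjusted p = 0.892 with an estimated correlation), as did cell cycle genes with 0 of 20 past the threshold (median 0.26, adjusted p = 0.0396, and adjusted p = 0.934 with an estimated correlation). The endothelial mean was 1.95 on the array of replicate 2 against 0.72 and 0.76 on the other two and 0.45 to 0.52 on chow. Without replicate 2 the endothelial median was 0.19 (adjusted p = 0.0201) and the calcium median -0.28 (0.00185), and without replicate 1 the adipocyte and cell cycle medians were 0.51 and 0.40.

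In all, 2036 genes passed in limma at 8 weeks in MuRF1 +/+, of which 760 rose and 1276 fell. The count was 634 without chow replicate 3, 938 without 8-week replicate 2, 989 without chow replicate 1 and 4781 without 8-week replicate 1. It was 1231 with slide as a block, 935 in the series matrix, 1205 with all spots in the background fit, 1310 without the 3-week arrays, 5496 with array weights, 56 with only these 2 groups in the fit and 74 with the Y-linked level as a covariate. With only these groups in the fit, Pdk4, Nmrk2, Cyp1a1, Actc1, Fbxo32, Ddx3y and Eif2s3y kept their calls and the other genes of this comparison named here lost theirs. In the series matrix Kcnq1, Myom2, Cpt1a, Ttn and Myh7 lost theirs. Cpt1a was lost also with all spots in the background fit, Myh7 also in Agilent's log ratio and the heart channel alone, and Pkm with slide as a block. Calls were also lost without chow replicate 3 for Cpt1a (adjusted p = 0.0552), Ccn2 (0.0511), Nr4a1 (0.101), Vwf (0.0865), Aqp1 (0.0599) and Myh7 (0.0771), and without 8-week replicate 2 for Cldn5 (0.0552), Pdhb (0.097), Pkm (0.0992), Ttn (0.0753), the extracellular matrix list (0.129) and the adipocyte list (0.163). Chow replicate 1 also ended the calls of Aqp1, Pdhb, Pkm, Ttn and Myh7, chow replicate 3 those of Pdhb, Pkm and Ttn, 8-week replicate 2 that of Vwf and 8-week replicate 3 that of Myh7. The immediate early list was lost without 8-week replicate 1 (0.0987) or chow replicate 3. The strict filter on dim probes ended the immediate early, adipocyte and cell cycle lists. The adipocyte list was also lost in Agilent's log ratio, the heart channel alone and the series matrix. The cell cycle list was lost in those, with all spots in the background fit, with slide as a block and without 8-week replicate 2 or 3 (0.143) or chow replicate 1 or 3. Within 2 single slides, 1 of them holding 8-week replicate 2, Pdk4 differed by 1.97 to 3.92, Acot1 by 1.69 to 3.17, Angptl4 by 1.28 to 2.42, Nmrk2 by -3.16 to -3.02 and Cyp1a1 by -2.73 to -1.65. List means differed within slides by 0.15 to 0.64 for PPAR alpha targets, 0.20 to 1.43 for endothelial, 0.070 to 0.83 for extracellular matrix genes. They differed by -0.40 to -0.16 for glycolysis, -0.89 to -0.30 for calcium handling, 0.40 to 0.57 for immediate early, 0.052 to 0.74 for adipocyte and -0.077 to 0.48 for cell cycle genes.

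In MuRF1 -/- hearts after 8 weeks of fenofibrate, Pdk4 was 5.32-fold higher than on chow (log2 2.41 ± 0.36, n = 3 against 3, adjusted p = 0.00132), Acot1 3.37-fold (1.75 ± 0.39, adjusted p = 0.0243) and Sqstm1, the autophagy adaptor p62, 2.69-fold (1.43 ± 0.16, adjusted p = 0.000144). Nmrk2 fell 7.11-fold (-2.83 ± 0.35), Cyp1a1 fell 3.16-fold (-1.66 ± 0.25) and Itgb6, an integrin subunit, fell 2.39-fold (-1.26 ± 0.15). PPAR alpha target genes rose as a list, with 2 of 28 past the threshold, and 2 adjusted over the list alone (median 0.13, adjusted p = 0.000392, and adjusted p = 0.889 with an estimated correlation). Without replicate 2, the heart of this group lacking Y-linked transcripts, their median was 0.077 (adjusted p = 0.0167). Myom2 rose 1.92-fold (0.94 ± 0.18) and Fbxo31 1.59-fold (0.67 ± 0.14), while Psmb9, an immunoproteasome subunit, fell (-0.68 ± 0.16). Macrophage and leukocyte genes fell as a list (1 of 20, 6 adjusted over the list alone, median -0.23, adjusted p = 0.00369, and adjusted p = 0.816 with an estimated correlation), the member being Adgre1, the macrophage marker F4/80 (-0.60 ± 0.14). Extracellular matrix genes fell with 0 of 26 past the threshold (median -0.21, adjusted p = 0.00386, 0.892 with an estimated correlation). Interferon response genes (0 of 23, 2 adjusted over the list alone, median -0.14, adjusted p = 0.0212, 0.892 with an estimated correlation) and smooth muscle genes (0 of 14, median -0.33, adjusted p = 0.0202, 0.889 with an estimated correlation) fell too.

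The limma count for 8 weeks in MuRF1 -/- was 264 genes, 125 up and 139 down. It was 72 and 123 without 8-week replicates 3 and 2, 94 without 8-week replicate 1, and 92, 141 and 146 without chow replicates 1, 2 and 3. It was 59 with slide as a block, 88 without the 3-week arrays, 135 with all spots in the background fit, 152 without a filter on dim probes, 155 with the Y-linked level as a covariate and 168 in the series matrix. It was higher, at 651, with only these 2 groups in the fit, at 917 without the 2 arrays that stood apart and at 1446 with array weights. The calls of Nmrk2, Cyp1a1 and Itgb6 were lost in the series matrix and with all spots in the background fit. Acot1 was lost with slide as a block and without 8-week replicate 2 (adjusted p = 0.129) or 3 or chow replicate 1 or 2. Myom2 was lost with slide as a block and without 8-week replicate 1 or 2 (0.0797) or chow replicate 1. Fbxo31, Psmb9 and Adgre1 were lost with slide as a block and without most single arrays (8-week replicate 1 and chow replicate 1 for all 3), with adjusted p up to 0.0957, 0.146 and 0.18. The extracellular matrix list (0.185) and the macrophage list (0.08) were lost without chow replicate 1. The interferon list was lost with slide as a block and without 8-week replicate 1 (0.223) or chow replicate 1 or 2, and the smooth muscle list without chow replicate 1 or 2 (0.0982), both also in the series matrix and with all spots in the background fit. Without chow replicate 3 the matrix and interferon medians were -0.34 and -0.26. The macrophage and smooth muscle lists were lost under the strict filter on dim probes. The 1 slide with both groups held 8-week replicate 2, which lacked Y-linked transcripts, and chow replicate 2, the array with spots left out of the background fit. These arrays had the highest 8-week and the lowest chow level of Pdk4 (2.65 and -0.82) and Acot1 (1.24 and -1.42) in MuRF1 -/-. On it Pdk4 differed by 3.47, Acot1 by 2.66, Nmrk2 by -2.42, Cyp1a1 by -2.15 and the list means by 0.56 for PPAR alpha targets, -0.21 for extracellular matrix, -0.24 for macrophage, -0.17 for interferon and -0.33 for smooth muscle genes.

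At 8 weeks, 72 genes rose and 91 fell in both genotypes, where independent lists of these sizes would share 6.52 and 12.2, and 0 were called in opposite directions by limma. Pdk4, Acot1, Nmrk2 and Cyp1a1 were among them. Across 14567 genes, which are not independent replicates, the log2 changes in the genotypes had a Pearson correlation of 0.298 and a Spearman correlation of 0.186. The correlation was -0.145 in the series matrix and -0.068 with all spots in the background fit, and 0.479 without 8-week MuRF1 +/+ replicate 2. The difference of the 8-week responses was past the threshold for 1 gene, Arhgef19, a guanine nucleotide exchange factor, whose response was higher in MuRF1 -/- by log2 0.72 ± 0.11 (adjusted p = 0.0398). Arhgef19 lies on chromosome 4, 86 tested genes from Trim63. Averaged over diets it was lower in MuRF1 -/- (log2 -0.32 ± 0.042, limma adjusted p = 0.000701). A genotype gap on chow enters the difference of responses with its sign turned. The call of Arhgef19 for this difference was lost with slide as a block and without any of MuRF1 -/- 8-week replicates 1, 2 and 3 (up to 0.206), MuRF1 -/- chow replicates 1 and 3, MuRF1 +/+ 8-week replicate 2 and MuRF1 +/+ chow replicates 1 and 3. The count was 0 without each of these except MuRF1 -/- 8-week replicate 2, 2 without that one, 2 without MuRF1 +/+ 8-week replicate 3, 12 without MuRF1 -/- chow replicate 2 and 1385 without MuRF1 +/+ 8-week replicate 1. The series matrix had 7 genes higher and 1 lower. The count was 6 with all spots in the background fit or without the 2 arrays that stood apart, 1853 with array weights and 2 in the heart channel alone. It was 0 in limma in Agilent's log ratio, under the strict filter on dim probes and with the Y-linked level as a covariate.

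Lists whose 8-week responses differed between genotypes in limma's camera included extracellular matrix genes, lower in MuRF1 -/- (median difference -0.59, 7 of 26 adjusted over the list alone, adjusted p = 1.67e-06, and adjusted p = 0.889 with an estimated correlation). Endothelial genes were lower (-0.63, adjusted p = 0.000131, 0.89 with an estimated correlation). Also lower were macrophage (-0.27), interferon (-0.27) and immediate early genes (-0.36). Their adjusted p were 0.0184, 0.0119 and 0.0392, and 0.889, 0.892 and 0.89 with an estimated correlation. Fatty acid oxidation (0.47), glycolysis (0.20) and calcium handling genes (0.41) were higher. Their adjusted p were 0.00537, 0.00537 and 0.0274, and 0.89, 0.344 and 0.889 with an estimated correlation. Each difference subtracts the genotype gap on the same chow hearts, and sex is not parted from it. On chow glycolysis genes were lower, and matrix, interferon and immediate early genes higher, in MuRF1 -/-. These gaps are opposite in sign to the differences. Of these lists only matrix genes had a list call for genotype at 8 weeks. Without MuRF1 +/+ 8-week replicate 2 the endothelial difference was -0.18 (adjusted p = 0.00926), the matrix difference -0.34 and the fatty acid oxidation difference 0.17 (0.0672), and without MuRF1 -/- chow replicate 3 the interferon difference was -0.45. Among arrays whose omission ended a list's call, the highest adjusted p was 0.0723 for calcium handling (without MuRF1 -/- chow replicate 1 or 2 or MuRF1 +/+ 8-week replicate 1 or 2 or chow replicate 3). It was 0.0848 for macrophage genes (without MuRF1 -/- 8-week replicate 2 or chow replicate 1 or MuRF1 +/+ 8-week replicate 1 or chow replicate 1). It was 0.0867 for interferon genes (without MuRF1 -/- 8-week replicate 1 or chow replicate 2 or MuRF1 +/+ 8-week replicate 1) and 0.214 for immediate early genes (without MuRF1 -/- 8-week replicate 2 or chow replicate 1 or 2 or MuRF1 +/+ 8-week replicate 1 or chow replicate 3). The macrophage and interferon differences were also lost in the series matrix and with all spots in the background fit, the calcium and immediate early differences in Agilent's log ratio, and the immediate early difference also in the heart channel alone, the series matrix and the mean of all probes. The strict filter on dim probes ended the calcium, macrophage and immediate early differences.

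**Figure D3:**
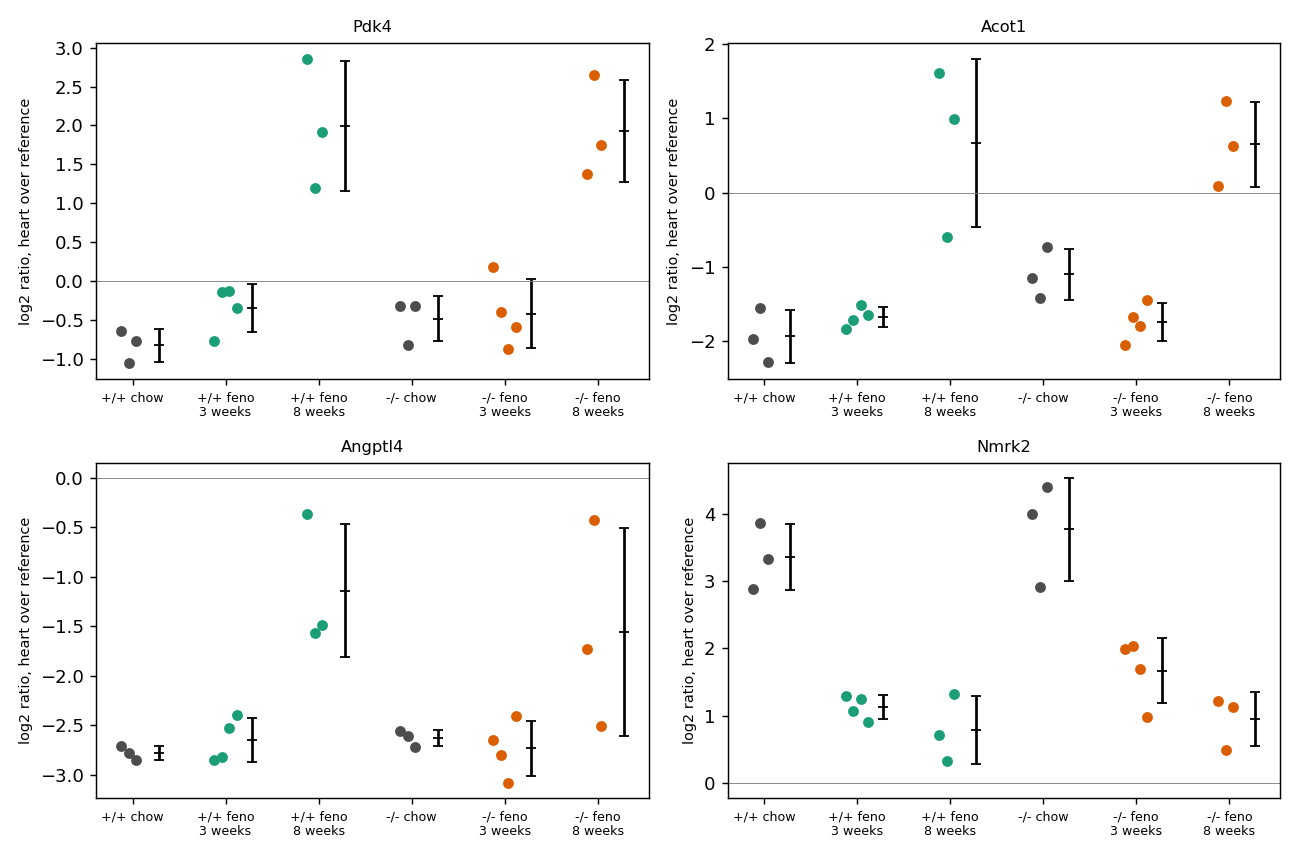
Log2 ratio of heart to reference for Pdk4, Acot1, Angptl4 and Nmrk2 in the 6 groups; points are arrays and bars are group means ± SD. Pdk4 is 7.06-fold higher at 8 weeks than on chow in MuRF1 +/+ and 5.32-fold higher in MuRF1 -/-, and Nmrk2 is lower on fenofibrate in both.

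After 3 weeks, MuRF1 +/+ hearts had 10.2-fold more Pinx1, a telomerase inhibitor (log2 3.35 ± 0.39, n = 4 against 3, adjusted p = 2.01e-05), though its other probe differed by 0.059. Srrm3, a splicing factor, rose 8.23-fold (3.04 ± 0.32), Nmrk2 fell 4.72-fold (-2.24 ± 0.33), Xist rose 13.6-fold (3.76 ± 0.32), and Eif2s3y (log2 ratio -2.44 ± 0.39) and Ddx3y (-2.19 ± 0.35) fell below background, at least 5.48-fold and 4.45-fold lower on the heart channel scale. Glycogen synthase Gys1 (-0.98 ± 0.15), hexokinase Hk1 (-0.85 ± 0.10) and phosphofructokinase Pfkl (-0.58 ± 0.10) fell, while Pfkfb2, which makes the activator fructose 2,6-bisphosphate, rose (0.76 ± 0.091). The glycolysis list did not pass (1 rose and 5 fell of 24, adjusted p = 0.217). Titin, Ttn, rose 3.92-fold (1.97 ± 0.30) and Trim55, the MuRF2 gene, rose 2.24-fold (1.16 ± 0.21). Of PPAR alpha target genes, 1 rose and 3 fell of 28 (0 of 28 passed adjusted over the list alone), and the list did not pass, with a median of 0.017 and a negative test (adjusted p = 0.546). Neither Pdk4 nor Acot1 passed there.

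Extracellular matrix genes rose as a list at 3 weeks in MuRF1 +/+ (7 rose and 1 fell of 26, 8 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.029, 0.892 with an estimated correlation). Col3a1 (1.13 ± 0.25, other probe 0.074), fibrillin Fbn1 (0.67 ± 0.14, other probe 0.285) and the fibroblast receptor gene Pdgfra (0.57 ± 0.12) rose, and Tgfb1 fell (-0.35 ± 0.060). Interferon response genes rose (3 of 23, median 0.21, adjusted p = 0.0432, 0.928 with an estimated correlation), with the guanylate-binding protein gene Gbp3 (0.64 ± 0.17). Acads, short-chain acyl-CoA dehydrogenase (-1.12 ± 0.28), and the peroxin gene Pex14 (-0.86 ± 0.13) fell. In all 3536 genes passed in limma, 1748 up and 1788 down, with 2157 up and 1401 down in Agilent's own log ratio. The count was 1966 without chow replicate 3, 2331 without chow replicate 1, 2923 with slide as a block, 2221 under the strict filter on dim probes and 339 with the Y-linked level as a covariate. It was higher, at 5819 with only these 2 groups in the fit and at 6803 with array weights. The matrix list was lost with slide as a block and without 3-week replicate 4 (0.112) or chow replicate 1 or 3, and the interferon list without 3-week replicate 1, 2 (0.117) or 4 or chow replicate 1 or 3. The matrix list was also lost in Agilent's log ratio, the heart channel alone and the mean of all probes. Within slides these list means differed by 0.19 to 0.21 and by 0.24 to 0.29, and Nmrk2 by -2.80 to -1.60.

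MuRF1 -/- hearts at 3 weeks had the same 3 leading rises, with Xist at a log2 ratio 3.86 ± 0.32 higher (at least 16.0-fold on the heart channel scale, from below background on chow), Pinx1 13.5-fold (log2 3.75 ± 0.39, other probe -0.029) and Srrm3 11.6-fold (3.54 ± 0.32, n = 4 against 3, adjusted p = 6.24e-07). Nppa, atrial natriuretic peptide, rose 2.04-fold (1.03 ± 0.19, adjusted p = 0.000846). Nmrk2 fell 4.31-fold (-2.11 ± 0.33), and Ddx3y (-2.32 ± 0.35) and Eif2s3y (-2.22 ± 0.39) fell. Interferon response genes rose as a list (11 of 23, 14 adjusted over the list alone, median 0.41, adjusted p = 0.000344, and adjusted p = 0.89 with an estimated correlation), with Gbp3 (0.97 ± 0.17), Irf9 (0.68 ± 0.14), Mx2 (0.54 ± 0.12) and Ifi44 (0.53 ± 0.12). Of PPAR alpha target genes 5 of 28 fell, 4 adjusted over the list alone, and the list did not pass (median -0.15, adjusted p = 0.0646). Plin5, a lipid droplet protein, fell 2.13-fold (-1.09 ± 0.19) and Pex11a fell (-0.70 ± 0.11). Gys1 (-1.04 ± 0.15), Hk1 (-0.80 ± 0.10), Acads (-1.38 ± 0.28), Pex14 (-1.04 ± 0.13) and the desmin gene Des (-1.75 ± 0.40) fell. Ttn (1.58 ± 0.30), Trim55 (1.41 ± 0.21), Myom2 (0.97 ± 0.15), Egfl7, an endothelial gene (0.88 ± 0.22), and Tek (0.54 ± 0.14) rose, and the junction gene Jph2 fell (-1.07 ± 0.26). In limma 3864 genes passed, 2098 up and 1766 down. The count was 2337 without chow replicate 3, 3406 with slide as a block, 2198 in the series matrix, 2345 with all spots in the background fit, 2399 under the strict filter on dim probes, 436 with the Y-linked level as a covariate and 5812 with array weights. Within slides Nmrk2 differed by -2.72 to -0.89 and the interferon list mean by 0.23 to 0.96. Nmrk2 was lost in the series matrix.

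At 3 weeks 1375 genes rose and 1245 fell in both genotypes, where independent lists would share 252 and 217, and 0 were called in opposite directions. Across genes, which are not independent replicates, the Pearson correlation was 0.904 and the Spearman correlation 0.848. The difference of the 3-week responses was past the threshold for 0 genes in limma, with 352 at unadjusted p under 0.05. The smallest p belonged to Arhgef19 (0.55 ± 0.10), the cytokine gene Il15 (1.88 ± 0.33, other probe 0.39) and Misp3 (0.72 ± 0.13), all at adjusted p = 0.117. On chow Il15 was lower in MuRF1 -/- (log2 -1.81 ± 0.25, other probe -0.24), a gap that enters its difference with the sign turned. The count was 1 without MuRF1 -/- 3-week replicate 3 or MuRF1 +/+ 3-week replicate 1, 2 without MuRF1 +/+ chow replicate 2 and 5 without MuRF1 -/- 3-week replicate 4. It was 6 without the 2 arrays that stood apart and 29 with array weights. The 3-week response of interferon genes was higher in MuRF1 -/- (median difference 0.18, adjusted p = 0.00149, and adjusted p = 0.892 with an estimated correlation). PPAR alpha targets (-0.080, adjusted p = 0.0129, 0.889 with an estimated correlation) and immediate early genes (-0.20, adjusted p = 0.00275, 0.889 with an estimated correlation) were lower. Interferon and immediate early genes were both higher in MuRF1 -/- on chow, a gap that each difference subtracts. The interferon difference was lost without MuRF1 -/- 3-week replicate 3 or chow replicate 3 (0.33) and in Agilent's log ratio, and the immediate early difference without MuRF1 -/- chow replicate 1 (0.164) or MuRF1 +/+ chow replicate 3. The PPAR alpha difference was lost without MuRF1 -/- 3-week replicate 3 or 4 or chow replicate 3 (0.0982) or MuRF1 +/+ chow replicate 3, with slide as a block, in the series matrix and with all spots in the background fit. It ran from -0.16 (without MuRF1 -/- 3-week replicate 4) to -0.032 (without replicate 1 of that group), and was -0.051 and -0.042 without MuRF1 +/+ 3-week replicates 3 and 4. The interferon difference was 0.29 without MuRF1 -/- 3-week replicate 4, and the immediate early difference -0.34 without MuRF1 -/- chow replicate 3.

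**Figure D4:**
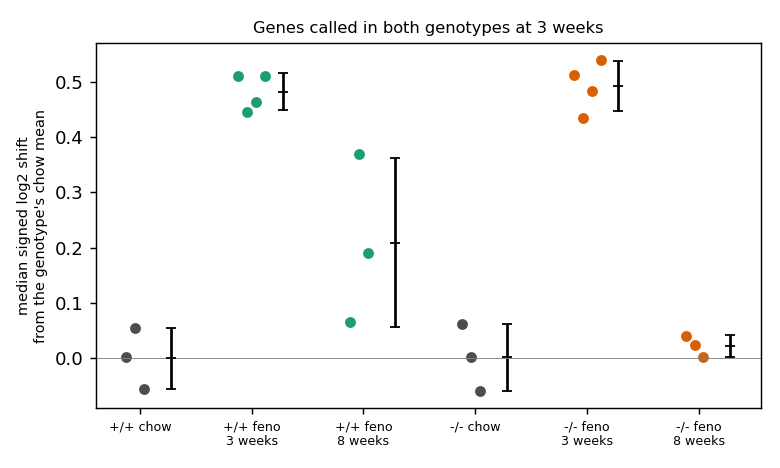
Median signed log2 shift, from the chow mean of the same genotype, of the 2620 genes called in both genotypes at 3 weeks, for each array; points are arrays and bars are group means ± SD. The median of the 3-week change is 0.485, and the 3 MuRF1 +/+ hearts at 8 weeks lie at 0.066, 0.37 and 0.19.

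Hearts at 8 weeks differed from those at 3 weeks, averaged over genotypes, by 5.50-fold more Myh7 (log2 2.46 ± 0.29, n = 6 against 8, limma adjusted p = 3.75e-06), 5.19-fold more Acot1 (2.38 ± 0.26) and 5.07-fold more Pdk4 (2.34 ± 0.24). In MuRF1 -/-, 2 of 3 hearts at 8 weeks and 0 of 4 at 3 weeks had both Y-linked transcripts. Sex is not parted from duration there. PPAR alpha target genes were higher at 8 weeks as a list (13 of 28 rose, 13 adjusted over the list alone, median 0.23, adjusted p = 0.000131, 0.816 with an estimated correlation), with Plin5 (0.90 ± 0.14) and Ucp2 (0.46 ± 0.057). Fbxo31 (1.13 ± 0.096), the transcription factor gene Hand2 (0.91 ± 0.11) and Ccn2 (1.55 ± 0.30) were higher. Interferon response genes were lower (13 of 23 fell, 15 adjusted over the list alone, median -0.35, adjusted p = 0.000373, 0.89 with an estimated correlation), among them Gbp3 (-1.03 ± 0.12). Srrm3 (-2.91 ± 0.23), Pinx1 (-3.04 ± 0.27), the vitamin A receptor gene Stra6 (-2.76 ± 0.24), Xist (-2.51 ± 0.23), Pfkfb2 (-1.01 ± 0.065), Trim55 (-1.04 ± 0.15), Ttn (-1.15 ± 0.21), Col3a1 (-1.24 ± 0.18) and lumican, Lum (-1.26 ± 0.19), were lower. Ptprz1 was higher (2.54 ± 0.48), but 1 of its 2 other probes had -0.83. In all 5385 genes passed, 2458 higher and 2927 lower at 8 weeks, and 4390 with slide as a block, of which 4329 were shared. The count was 3553 under the strict filter on dim probes and 8172 with array weights.

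Averaged over genotypes and durations, Nmrk2 was 5.43-fold lower on fenofibrate (log2 -2.44 ± 0.21, n = 14 against 6, limma adjusted p = 1.28e-06), Cyp1a1 3.67-fold (-1.87 ± 0.15) and Alas1, the first enzyme of heme synthesis, 2.01-fold (-1.01 ± 0.068, adjusted p = 1.5e-07). Outside 8-week MuRF1 -/- hearts, sex is not parted from diet here. Also among the 12 largest falls were Eif2s3y (-1.88), Ddx3y (-1.85), Dipk1b (-1.33), the F-box gene Fbxl22 (-1.23), the adenylyl cyclase gene Adcy5 (-1.12), Klhdc8a (-1.10), Mov10l1 (-1.09), Cited4 (-1.06) and the potassium channel gene Kcnj14 (-1.04). The largest rises were Xist (2.55 ± 0.20), Pinx1 (2.03), Srrm3 (1.83), Stra6 (1.67), Neat1 (1.66) and Malat1 (1.46), nuclear long noncoding RNAs, L3mbtl2 (1.64), Ddx42 (1.45), Pdk4 (1.44 ± 0.21), Ing5 (1.39), Gabbr2 (1.33) and Pdia5 (1.30). Other probes of Pinx1, L3mbtl2, Gabbr2, Ddx42 and Fbxl22 had -0.047, -0.25, 0.046, 0.21 and -0.31, and those of Ing5 0.023 and 0.16. Those of Xist, Malat1, Ddx3y, Adcy5, Alas1 and Cited4 moved by 0.519 or more the same way. Calcium handling genes fell as a list (8 of 18, 9 adjusted over the list alone, median -0.26, adjusted p = 0.0136, 0.889 with an estimated correlation), with Jph2 (-0.82 ± 0.17) and Casq2 (-0.55 ± 0.13). Endothelial genes rose (8 rose and 1 fell of 20, 11 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.0152, 0.895 with an estimated correlation), with Aqp1 (0.93 ± 0.22) and Vwf (0.64 ± 0.15). PPAR alpha targets went both ways (6 rose and 3 fell of 28, 6 and 4 adjusted over the list alone, adjusted p = 0.755). In all 4408 genes passed, 2158 up and 2250 down. The count was 3528 with slide as a block, 2045 in the series matrix, 2418 with all spots in the background fit, 120 with the Y-linked level as a covariate, 1314 without the 3-week arrays and 6819 with array weights. Adcy5, Kcnj14 and Mov10l1 were lost in the series matrix, Mov10l1 also with all spots in the background fit and in Agilent's log ratio, where Kcnj14 had 0.076, and the calcium list in the series matrix and with all spots.

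Genotype calls on chow numbered 13, 5 up and 8 down in MuRF1 -/- (n = 3 against 3). Klhl31, a kelch-like protein of muscle, was 4.89-fold higher (log2 2.29 ± 0.24, limma adjusted p = 7.68e-05, other probe 0.0018), and Kpna2, an importin (1.06 ± 0.17), and Snap91, a clathrin assembly protein (1.04 ± 0.16), were higher. Il15 was 3.52-fold lower (-1.81 ± 0.25, other probe -0.24) and Gadd45gip1 was lower (-1.05 ± 0.18, other probe 0.042). Glycolysis genes were lower as a list with 0 of 24 past the threshold (median -0.17, adjusted p = 0.00116, and adjusted p = 0.323 with an estimated correlation). Interferon (0.14), immediate early (0.16) and extracellular matrix genes (0.13) were higher. Their adjusted p were 0.0012, 0.00196 and 0.0123, and 0.89, 0.889 and 0.892 with an estimated correlation. The count was 5 without MuRF1 -/- chow replicate 1 or MuRF1 +/+ chow replicate 3, and 10 with slide as a block. It was 6 without the 3-week arrays, 8 under the strict filter on dim probes, 51 with array weights, and 4 up and 4 down in the heart channel alone. Kpna2 (up to 0.0884), Snap91 (0.0774) and Gadd45gip1 (0.2) were lost without either of those arrays, Kpna2 and Gadd45gip1 also without MuRF1 -/- replicate 2 or MuRF1 +/+ replicate 1, and Gadd45gip1 without MuRF1 -/- replicate 3. The matrix list was lost without MuRF1 -/- replicate 1 (0.799) or MuRF1 +/+ replicate 1 or 3. The immediate early list was lost without MuRF1 -/- replicate 1 or MuRF1 +/+ replicate 3 (0.186) and the interferon list without MuRF1 -/- replicate 2 (0.164), in the series matrix and with all spots in the background fit. Il15 was lost in Agilent's log ratio, Kpna2 in the series matrix, Snap91 with slide as a block and Gadd45gip1 in the heart channel alone. The matrix and immediate early medians were 0.21 and 0.26 without MuRF1 -/- replicate 3, and the interferon median 0.069 without MuRF1 +/+ replicate 1. Within the 2 slides that held both groups, the list means differed by -0.28 and -0.20 for glycolysis and by 0.074 and 0.31 for immediate early genes. They went both ways for interferon (-0.081 and 0.27) and extracellular matrix genes (-0.016 and 0.39).

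At 3 weeks of fenofibrate, 58 genes differed by genotype, 52 higher and 6 lower in MuRF1 -/- (n = 4 against 4). Klhl31 was 2.55-fold higher (log2 1.35 ± 0.21, limma adjusted p = 0.0058) and Med1, a mediator subunit, 1.95-fold higher (0.97 ± 0.10), with its 2 other probes at -0.0012 and 0.16. Adat2, a tRNA deaminase subunit (-0.93 ± 0.11), and Hars, histidyl-tRNA synthetase (-0.92 ± 0.13), were lower. Interferon genes were higher as a list (2 of 23, 11 adjusted over the list alone, median 0.29, adjusted p = 1.27e-14, and adjusted p = 0.659 with an estimated correlation). Hypertrophy and fetal genes were higher (1 of 22, median 0.11, adjusted p = 0.00258, 0.323 with an estimated correlation), and glycolysis genes were lower (0 of 24, median -0.13, adjusted p = 0.0046, 0.344 with an estimated correlation). Within slides these list means differed by -0.037 to 0.32, 0.20 to 0.26 and -0.16 to -0.12. The count was 10 without MuRF1 -/- replicate 1 or MuRF1 +/+ replicate 3, 22, 30 and 33 without MuRF1 +/+ replicates 4, 2 and 1, and 29 and 112 without MuRF1 -/- replicates 2 and 4. It was 18 with slide as a block, 6 with only these 2 groups in the fit, 12 under the strict filter on dim probes, 21 with all spots in the background fit, 36 with the mean of all probes, 191 without the 2 arrays that stood apart and 303 with array weights. It was 5 higher and 5 lower in Agilent's log ratio and 5 and 4 in the series matrix. Klhl31 was lost with only these 2 groups in the fit, and the hypertrophy list with the mean of all probes of a gene.

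At 8 weeks, 11 genes differed by genotype, 6 higher and 5 lower in MuRF1 -/- (n = 3 against 3). Klhl31 was 3.07-fold higher (log2 1.62 ± 0.24, limma adjusted p = 0.00874) and Efnb3, an ephrin (1.16 ± 0.19), was higher, while Serinc3 (-1.33 ± 0.20) and the zinc finger gene Zfp985 (-0.76 ± 0.11) were lower. Extracellular matrix genes were lower as a list (0 of 26, 13 adjusted over the list alone, median -0.42, adjusted p = 2.1e-06). So were endothelial (0 of 20, 7 adjusted over the list alone, median -0.57, adjusted p = 1.67e-06) and smooth muscle genes (0 of 14, 8 adjusted over the list alone, median -0.48, adjusted p = 0.0325). Fatty acid oxidation (median 0.43, adjusted p = 0.000789), sarcomere (0.17, adjusted p = 0.0152) and calcium handling genes (0.35, adjusted p = 0.0129) were higher. All of these lists had adjusted p = 0.889 with an estimated correlation. The count was 1, 22 and 2 without MuRF1 -/- replicates 1, 2 and 3, 3076 and 214 without MuRF1 +/+ replicates 1 and 3, 2 with slide as a block, and 70 higher and 107 lower in Agilent's log ratio. It was 1 with only these 2 groups in the fit, 2 with the Y-linked level as a covariate, 5 with all spots in the background fit, 7 without the 3-week arrays, 25 without the 2 arrays that stood apart, 102 in the heart channel alone, 112 under the strict filter and 2423 with array weights. Klhl31 (0.0505), Efnb3, Serinc3 and Zfp985 were lost without MuRF1 -/- replicate 1, the last 3 also with slide as a block and without MuRF1 -/- replicate 3 (0.125, 0.0734 and 0.0608), and Efnb3 without MuRF1 +/+ replicate 2. Without MuRF1 +/+ replicate 2, which stood apart, the medians were -0.16 for endothelial (0.000532), -0.23 for matrix, -0.23 for smooth muscle, 0.15 for fatty acid oxidation (0.026), 0.084 for sarcomere and 0.15 for calcium handling genes (0.0364). The strict filter on dim probes ended the calcium and smooth muscle calls, and without MuRF1 -/- replicate 3 the sarcomere list was lost (0.23), as it was with the mean of all probes. With only these 2 groups in the fit Klhl31, Efnb3, Serinc3, Zfp985 and the smooth muscle list were lost, the smooth muscle list also with slide as a block and Zfp985 also in the series matrix and with all spots in the background fit. Within slides the matrix list differed by -0.29 to -0.21, the endothelial list by -0.28 to -0.26, the smooth muscle list by -0.34 to -0.16 and the calcium handling list by 0.097 to 0.11. The fatty acid oxidation (-0.075 to 0.35) and sarcomere lists (-0.50 to 0.12) went both ways.

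Averaged over the diet groups, 28 genes differed by genotype, 14 higher and 14 lower in MuRF1 -/- (n = 10 against 10), and 6 and 13 in the series matrix. Klhl31 was 3.37-fold higher (log2 1.75 ± 0.13, limma adjusted p = 3.9e-07), Med1 1.87-fold (0.90 ± 0.064) and Kpna2 1.70-fold (0.76 ± 0.095). Below Trim63, the largest falls were Abhd1 (-1.54 ± 0.28), Rprd1b (-1.18 ± 0.16), Il15 (-0.83 ± 0.14), Hars (-0.75 ± 0.083), Serinc3 (-0.73 ± 0.11), Adat2 (-0.69 ± 0.069), Zfp933 (-0.68 ± 0.072, other probe 0.031), Gadd45gip1 (-0.64), Zfp985 (-0.45), the complex I assembly gene Timmdc1 (-0.39) and Zfp987 (-0.35). Znf41-ps was 0.62 ± 0.10 higher at the tested probe, but its 3 other probes ran from -0.47 to -0.22 and the mean of its probes gave -0.13. Interferon genes were higher as a list (median 0.12, adjusted p = 0.000102, and adjusted p = 0.889 with an estimated correlation), and endothelial genes were lower (-0.17, adjusted p = 0.000864, 0.892 with an estimated correlation; 0.403 without MuRF1 +/+ 8-week replicate 2). With slide as a block 27 genes passed, 23 of them shared, and without MuRF1 +/+ 8-week replicate 1 the count was 46. It was 17 without the 3-week arrays, 18 with all spots in the background fit, 69 without the 2 arrays that stood apart and 496 with array weights. Abhd1 was lost with slide as a block and without MuRF1 +/+ chow replicate 3 (0.0531). Zfp985, Zfp987 and Znf41-ps were lost in the series matrix and with all spots in the background fit, Gadd45gip1 and Zfp987 in the heart channel alone, Timmdc1 with the mean of all probes and the interferon list in Agilent's log ratio. Sarcomere (median 0.032, adjusted p = 0.0194) and hypertrophy genes (0.067, adjusted p = 0.0242) were higher as lists. Extracellular matrix (-0.086, adjusted p = 0.0242) and smooth muscle genes (-0.096, adjusted p = 0.0117) were lower. With an estimated correlation these had adjusted p = 0.889, 0.659, 0.892 and 0.889. The sarcomere list was lost without MuRF1 +/+ 8-week replicate 2 (0.138) or 3-week replicate 3 or MuRF1 -/- 3-week replicate 1, 8-week replicate 3 or chow replicate 1, and the smooth muscle list without MuRF1 -/- 3-week replicate 4 (0.0722). The matrix list was lost without MuRF1 +/+ 8-week replicate 2 (0.512), 3-week replicate 4 or chow replicate 2 or MuRF1 -/- 3-week replicate 2 or 3 or chow replicate 3. The hypertrophy list was lost without any of 8 single arrays, MuRF1 -/- chow replicate 1 (0.095), 3-week replicates 1 and 4 and 8-week replicate 3, and MuRF1 +/+ chow replicates 1 and 3, 3-week replicate 3 and 8-week replicate 3. The sarcomere median ran from 0.020 (without MuRF1 +/+ 3-week replicate 3) to 0.085 (without MuRF1 -/- 3-week replicate 4) over the arrays left out. The hypertrophy median was 0.027 without MuRF1 +/+ 8-week replicate 2, the smooth muscle median -0.15 without MuRF1 +/+ 8-week replicate 1 and the interferon median 0.052 without MuRF1 -/- 3-week replicate 3 (0.0118). The series matrix and the mean of all probes ended the calls of the sarcomere, hypertrophy and matrix lists, and slide as a block those of the matrix and smooth muscle lists. The strict filter on dim probes and all spots in the background fit ended the hypertrophy and matrix lists, and the heart channel alone the matrix list.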

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

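The results in this part came from rules set before the data were examined, and no test here was chosen only after the result was seen.

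Single arrays lay far from the other 3 of their group in 22 of 424 groups of 4 arrays, where chance gives about 1 in 20, or 21.2. Each ratio below is the gap to the nearest array over the range of the group. In the 3-week MuRF1 -/- group, replicate 4 stood apart for Adcy5 (ratio 0.845), Casq2 (0.932), Cidea (0.893), Eno3 (0.843), Klhdc8a (0.836), Mcm6 (0.944), Psmb9 (0.864), S100a8 (0.92), S100a9 (0.889) and the monocarboxylate transporter gene Slc16a10 (0.98). For Casq2 its log2 ratio was 0.20, where the other arrays had 0.90 to 0.95. The neutrophil genes S100a8 and S100a9 were at -2.12 and -4.07 there, and at -2.99 to -2.92 and -4.92 to -4.83 on the other arrays. Replicate 1 of that group stood apart for the cardiac transcription factor gene Gata4 (0.895), Med1 (0.867) and the mean of respiratory chain genes (0.858). This array had 1.20 for Med1, and the other arrays 0.98 to 1.01.

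In the 3-week MuRF1 +/+ group, replicate 4 stood apart for Ech1 (0.831), Hars (0.94), the atrial myosin light chain gene Myl7 (0.958) and Stmn1 (0.865). Hars was at -0.45 on that array and between -0.0090 and 0.019 on the others. Replicate 3 stood apart for Cidea (0.879) and Gbp3 (0.914), replicate 2 for Hand2 (0.871), and replicate 1 for Hk1 (0.947) and Rprd1b (0.947). Rprd1b was at -0.86 on replicate 1 and at 0.49 to 0.56 on the other arrays.

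Responses to fenofibrate that differed between genotypes, by a test of the difference itself, comprised 1 gene and 11 lists. At 8 weeks the gene was Arhgef19 (MuRF1 -/- minus MuRF1 +/+, log2 0.717). The median differences of the lists at 8 weeks were 0.467 for fatty acid oxidation, 0.204 for glycolysis, 0.409 for calcium handling, -0.585 for extracellular matrix, -0.265 for macrophage, -0.274 for interferon, -0.625 for endothelial and -0.355 for immediate early genes. At 3 weeks they were -0.0802 for PPAR alpha targets, 0.18 for interferon and -0.203 for immediate early genes. All 11 list differences rest on a preset correlation, and 0 of them passed in limma's camera with an estimated one. Each difference also subtracts the genotype gap on the same chow hearts, and the 8-week ones are not parted from sex.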

How the results depend on the processing

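The fits with all spots in the background correction, with the Y-linked level as a covariate, without the 2 arrays that stood apart and without the 3-week arrays were chosen only after the data were seen. The cause was not tested for the shifts below, apart from settings that hold fewer arrays or genes by construction. Gene and list calls were recomputed one by one under every setting except the Y-linked covariate and the fits without the 2 arrays or the 3-week arrays, which gave counts only. Apart from leaving out single arrays, gene calls stayed on the same side of the threshold with the same direction in 5249 cases, were lost in 599 and reversed in 2, and list calls stayed in 615 and were lost in 63. No background subtraction, Aquantile normalization and slide as a random block (within-slide correlation -0.0453) moved no count of genes by over 1.5 times.

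Under slide as a fixed block, 1231 genes passed at 8 weeks in MuRF1 +/+, 59 at 8 weeks in MuRF1 -/-, 18 for genotype at 3 weeks, 2 for genotype at 8 weeks and 0 in limma for the difference of the 8-week responses. That difference had 2433 genes at unadjusted p under 0.05 without the block. In Agilent's log ratio the genotype counts were 10 at 3 weeks and 177 at 8 weeks, and the 8-week difference had 0. The 8-week correlation there between genotypes was 0.198 and Kcnj14 averaged over fenofibrate groups turned to 0.0763. The heart channel alone gave 8 for genotype on chow, 102 for genotype at 8 weeks and 2 for the 8-week difference. In the series matrix the counts were 935 at 8 weeks in MuRF1 +/+, 2198 and 168 at 3 and 8 weeks in MuRF1 -/-, 9 for genotype at 3 weeks, 8 for the 8-week difference and 2045 for fenofibrate averaged. The correlations between genotypes were 0.755 at 3 weeks and, turned in sign, -0.145 at 8 weeks. Without a filter on dim probes 152 genes passed at 8 weeks in MuRF1 -/-. The strict filter, which tests fewer genes, gave 2221 and 2399 at 3 weeks in MuRF1 +/+ and -/-, 8, 12 and 112 for genotype on chow, at 3 and at 8 weeks, 0 for the 8-week difference and 3553 for 8 against 3 weeks. The mean of all probes gave 36 for genotype at 3 weeks and turned Znf41-ps, averaged over diets, to -0.129.

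With only the groups of a comparison in the fit, 5819 and 56 genes passed at 3 and 8 weeks in MuRF1 +/+, 651 at 8 weeks in MuRF1 -/-, and 6 and 1 for genotype at 3 and 8 weeks. Array weights raised every count, to 6803 and 5496 at 3 and 8 weeks in MuRF1 +/+, 5812 and 1446 in MuRF1 -/-. They became 51, 303, 2423 and 496 for genotype on chow, at 3 weeks, at 8 weeks and averaged, 29 and 1853 for the differences at 3 and 8 weeks, 6819 for fenofibrate averaged and 8172 for 8 against 3 weeks. The 3-week correlation was 0.857.

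With all spots in the background fit, the counts were 1205 at 8 weeks in MuRF1 +/+, and 2345 and 135 at 3 and 8 weeks in MuRF1 -/-. They were 21, 5 and 18 for genotype at 3 weeks, at 8 weeks and averaged, 6 for the 8-week difference and 2418 for fenofibrate averaged. Here the correlations were 0.766 at 3 weeks and, turned in sign, -0.068 at 8 weeks. The Y-linked covariate gave 339 and 74 at 3 and 8 weeks in MuRF1 +/+, 436 and 155 in MuRF1 -/-, 2 for genotype at 8 weeks, 0 for the 8-week difference and 120 for fenofibrate averaged. Without the 2 arrays that stood apart, 917 passed at 8 weeks in MuRF1 -/-, 191, 25 and 69 for genotype at 3 weeks, at 8 weeks and averaged, and 6 for each difference. Without the 3-week arrays, 1310 and 88 passed at 8 weeks in MuRF1 +/+ and -/-, 6, 7 and 17 for genotype on chow, at 8 weeks and averaged, and 1314 for fenofibrate averaged.

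Leaving out single arrays gave 1966 to 3023 and 634 to 4781 genes at 3 and 8 weeks in MuRF1 +/+, 2337 to 3987 and 72 to 146 in MuRF1 -/-. It gave 5 to 13, 10 to 112, 1 to 3076 and 25 to 46 for genotype on chow, at 3 weeks, at 8 weeks and averaged. The differences had 0 to 5 at 3 weeks and 0 to 1385 at 8 weeks, fenofibrate averaged 3118 to 5423 and 8 against 3 weeks 4699 to 6314. The correlations ran from 0.832 to 0.916 and from 0.175 to 0.479. Of gene calls 4538 stayed and 490 were lost, and of list calls 426 stayed and 77 were lost. Both the 634 (without chow replicate 3) and the 3076 and 1385 (without MuRF1 +/+ 8-week replicate 1) leave 2 arrays in a group, whose spread limma pools with the other groups.

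The replicate number as a block gave 0 genes for the 8-week difference and moved no other count by over 1.5 times. It ended 38 gene or list calls, among the lists that of extracellular matrix genes at 3 weeks in MuRF1 +/+. The numbers did not pair the arrays. Over 46 pairs of arrays with the same number in different groups, the deviations from the group means had a mean correlation of -0.00174 (from -0.58 to 0.451, 16 over 0.1). Other pairs had 0.000979, and 5 of 20 arrays correlated best with one of their own number. Arrays of one slide had a mean of -0.0347 and arrays of different slides 0.00792. Signal over background limits the dimmer probes, and a fold against a group below background is only a bound.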

Other observations

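The tests of sex, the test of slide for the 8-week genes and both tests of linked DNA on the chromosome of Trim63 were chosen only after the result was seen, and the other tests here were set before.

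Peroxisomal genes fell singly at 3 weeks in both genotypes, 6 of 21 in MuRF1 +/+ and 4 in MuRF1 -/-, and the list did not pass in either (adjusted p = 0.0868 and 0.255). At 8 weeks 6 of 21 were higher than at 3 weeks and 1 was lower (adjusted p = 0.0868), among them the import gene Pex14 (log2 0.81 ± 0.088), the bifunctional enzyme gene Hsd17b4 (0.48 ± 0.068) and Pex16 (0.59 ± 0.087). Of respiratory chain genes, 2 of 31 were up at 3 weeks in MuRF1 +/+, 6 were up in MuRF1 -/-, and 11 were lower at 8 than at 3 weeks, without a list call (median -0.23, adjusted p = 0.0598), such as Ndufa4 (-0.64 ± 0.13). Among 15 circadian clock genes, 1 rose and 5 fell at 3 weeks in MuRF1 +/+ and 3 fell in MuRF1 -/-, without a list call (adjusted p = 0.255 and 0.247). The clock repressor gene Nfil3 fell in both (-0.65 ± 0.18 and -0.76 ± 0.18), and was 0.96 ± 0.13 higher at 8 than at 3 weeks, as was Cry2 (0.48 ± 0.094). The call of Nfil3 in MuRF1 +/+ was lost without chow replicate 3 (0.073).

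Thyroid hormone responsive genes gave no list call, with 3 of 16 down at 3 weeks in MuRF1 +/+ (adjusted p = 0.356), where Klf9 fell (-0.67 ± 0.15, other probe -0.097). Averaged over fenofibrate groups, 1 rose and 1 fell of 17 skeletal muscle genes (adjusted p = 0.292), 1 and 1 of 12 atrial genes (0.821) and 4 and 5 of 26 neighbours of Trim63 (0.821). There 0 of 7 erythrocyte genes passed in limma (list adjusted p = 0.943), of which 1 fell at 8 weeks in MuRF1 +/+. Of the sex-linked list 4 of 5 genes were measured, too few for a list test.

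The 2620 genes called the same way in both genotypes at 3 weeks shifted by a median of 0.485, while the shifts of 8-week MuRF1 -/- hearts from chow were 8.4%, 4.75% (replicate 2, which lacked Y-linked transcripts and had Xist at -2.72) and 0.344% of that. Slide as the whole cause is argued against, since 4390 genes passed for 8 against 3 weeks with slide as a block, 4329 of them among the 5385 without it. Sex may account for part of it: the 8-week MuRF1 +/+ hearts, which also lacked Y-linked transcripts above background, shifted by 0.0659, 0.37 and 0.19, or 13.6%, 76.2% and 39.2%, and their Xist levels of -2.70, -0.90 and -2.05 stood in the same order. RNA integrity or probe position stays open too, as other probes of the 3-week genes carried 0.398 of the change and those of the 8-week genes 0.348, a difference of 0.0496 with a 95% bootstrap interval from -0.117 to 0.156. Other probes had the opposite sign for 18.9% and 7.81% of these genes, and the share of heart probes above background was 40.8% to 51.9% on all 3-week arrays but one (34.3%), against 34.0% to 44.2% on the others, while duration and age stay open as no chow heart belongs to 3 weeks.

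The 163 genes called the same way in both genotypes at 8 weeks had a median signed change of 0.597 in MuRF1 -/-. As they were selected for passing there, that median decides nothing, and the shared genes were chosen anew in each fit below. Sex as the whole cause is argued against by the fit without replicate 2, the heart of that group lacking Y-linked transcripts, which leaves 2 hearts with the Y-linked pattern of chow: limma called 80 genes the same way in both genotypes and 0 in opposite ways, where independent lists would share 7.43, and 74.0% of the 2036 genes called in MuRF1 +/+ had the same sign in MuRF1 -/-. Slide as the whole cause is argued against by 51 genes against 2.46 with slide as a block, though with both changes together only 10 were shared against 0.438. An effect of fenofibrate in both genotypes is a hypothesis, found and tested on the same data.

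Genotype calls averaged over diets lay on chromosome 4, which carries Trim63, in 7 of 23 placed cases apart from Trim63 (30.4%), against 6.25% of tested genes (odds ratio 6.61, Fisher's exact test, two-sided p = 0.000368), and in 1 of 12 on chow (odds ratio 1.36, exact p = 0.539), 4 of 33 at 3 weeks (2.07, exact p = 0.148) and 4 of 10 at 8 weeks (10.0, exact p = 0.00235). Of the 7, 5 are zinc finger genes, Zfp933, Zfp982, Zfp985, Zfp987 and Znf41-ps, which lie together 109 to 115 tested genes from Trim63, and other probes of Zfp933, Zfp982 and Znf41-ps had the opposite sign. Counted as 1 call, they leave 3 of 19 calls on the chromosome (odds ratio 2.83, exact p = 0.111), so whether calls gather there cannot be told. Arhgef19, called for the 8-week difference, is another of the 7. DNA of the donor strain that stayed linked to the targeted locus is a candidate explanation, as is a probe that binds several zinc finger transcripts. A list of the nearest neighbours, fixed beforehand, did not pass (adjusted p = 0.91), and an effect of MuRF1 itself stays open as untested.

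Other splits of the arrays bear on chance, unadjusted over comparisons. Each number of splits given here counts the real grouping as 1 of them. Few gave as many genes at 3 weeks in MuRF1 +/+ (1 of 35 splits, 3536 against a highest other of 572). MuRF1 -/- had 1 of 35 (3864 against 2110). Few did for fenofibrate averaged (1 of 100, 4408 against 0) and 8 against 3 weeks (1 of 100, 5385 against 3926). Genotype averaged had 2 of 100 (28 against 410), and the 410 leave chance open. Chance was not excluded for genotype at 3 weeks (2 of 35, 58 against 73) or the 8-week difference (13 of 100, 1 against 1735). For the 3-week difference the splits decide nothing, since with 0 genes in limma (352 at unadjusted p under 0.05) all 100 of 100 splits give as many, the highest other being 174. With 10 splits, too few for a share under 0.05, the real value and the highest other were 2036 and 2 at 8 weeks in MuRF1 +/+ and 264 and 0 in MuRF1 -/-. They were 13 and 1 for genotype on chow and 11 and 0 for genotype at 8 weeks. The split with 410 genes calls several times the real count, and what sets its arrays apart was not tested. The split with 1735 genes also does, but it exchanged the diets in MuRF1 -/- alone, which turns the sign of that response, and the split with 174 exchanged them for all MuRF1 -/- arrays but 3-week replicate 4. Likewise the split with 2110 genes at 3 weeks in MuRF1 -/- exchanged diets for all arrays but replicate 4.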
